A study of Mus musculus with 4 samples.

How the data were processed

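Bulk RNA sequencing was done on brain cortex of 10-month-old mice carrying the fro mutation of Smpd3, in 4 libraries: 2 from heterozygous fro/+ animals (replicates 5 and 8) and 2 from homozygous fro/fro animals (replicates 6 and 7). Per the labels' protocols, total RNA was extracted from fresh cortex with a column kit and 0.4 µg went into library preparation with the NEBNext Ultra 2 kit at a sequencing provider. The strain label gives a mixed C3H and C57BL/6 background for all 4 libraries. Each library had its own label, but nothing in the labels states that they came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

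The deposited table lists 21740 genes, each with at least 1 read over the 4 libraries. Its read counts per gene are whole numbers that, per the submitters' processing notes, came from STAR alignment to mm10 and featureCounts. Tool versions, the strand setting and the treatment of reads that align to several places are not given in the sources used here. The same table holds the authors' size-factor normalized signal: within each library the ratio of the deposited count to this value was the same for every gene. Its deposited FPKM values equalled the counts divided by the deposited gene length and the column total. The authors' log2 fold change of fro/fro over fro/+ and its p-value and adjusted p-value are given per gene, and DESeq2 is named in the submitters' processing notes. The deposited adjusted p-value is empty for 11415 genes. Gene coordinates and the gene length in base pairs were taken from the deposited table, in mm10.

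The raw counts were used for all tests. Genes were filtered with filterByExpr by genotype, which kept 15586 genes, and library sizes were scaled by TMM. The test was the quasi-likelihood test of edgeR 4.0.16 (robust fit, two-sided, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was the fold change divided by the square root of F. Values per library are counts scaled by TMM library size (CPM), as mean ± SD over the 2 libraries of a genotype. No paired analysis was possible because the genotypes share no replicate number.

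Library totals were between 21007254 and 25720347 counts. Simulated counts were drawn from the mean levels, dispersions and library sizes of these libraries, with 15348 genes run. The edgeR test recovered 16 of 50 genes changed by 1.5-fold and 36 of 50 changed by 2-fold. It recovered 49 of 50 changed by 4-fold and 49 of 50 changed by 8-fold. There were 26 false calls, a larger share of all calls in that simulation than the adjusted threshold is meant to allow. Calls just under the threshold in these data are therefore to be read with caution. With a simulated length trend over 15291 genes, the offset described next lowered the false calls from 59 to 21. That trend was put into the fro/fro libraries only and was milder than the real one. The rank correlation of fold change with gene length was 0.45 in the simulation and 0.55 in the data. The simulation therefore does not show how well the offset works on these libraries.

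There were 29 gene lists, fixed before the data were examined, of which 28 had at least 5 tested genes. They cover sphingolipid metabolism, exosome and ESCRT genes, immediate early genes, synaptic plasticity, senescence and SASP, oxidative stress response, astrocyte markers, reactive astrocyte genes, microglia markers, oligodendrocyte and myelin genes, oligodendrocyte precursor markers, endothelial and mural markers, excitatory and inhibitory neuron markers, markers of choroid plexus, striatum, hippocampus and thalamus, meninges and fibroblast markers, blood cell genes, interferon response, heat shock and unfolded protein response, cholesterol synthesis, circadian clock, amyloid and brain ageing genes, mitochondrially encoded genes, cytosolic ribosomal proteins and nuclear oxidative phosphorylation. The sex-linked list had 4 tested genes and was not tested as a set. Lists were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), adjusted over the 28 lists, and again with an estimated correlation and with fry. With 4 libraries the test with an estimated correlation has few degrees of freedom, and 0 of the 28 lists passed it. Not passing it therefore says little about any single list. Fry asks whether the genes of a list move one way on balance, without comparing them with other genes.

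Named genes followed a rule fixed before the data were examined. It took Smpd3, then the 12 called genes with the largest fold change in each direction, protein coding first, with a mean count of at least 50 and no overlap between genotypes. It also took up to 4 genes per list with the smallest p, the sex-linked genes, and called genes within 10 Mb of Smpd3. Genes named outside the rule are said to be chosen after their values were seen. The share of called genes within 10 Mb of Smpd3 was compared with the rest of the genome by a two-sided Fisher's exact test.

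The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, a mean count of at least 50, each library left out, removal of sex-linked genes, an adjusted threshold of 0.10, at least 1.5-fold change, windows of 5 and 20 Mb and the whole chromosome, and omission of genes within 10 Mb of Smpd3. After fold changes were seen to follow gene length, 3 alternatives were added, each a per-library offset from splines with 5 degrees of freedom: on the deposited gene length, on the length of 1 principal transcript per gene, and on transcript length with GC content. Principal transcripts came from GENCODE M21 (GRCm38), in which 21518 of the 21740 gene identifiers were found. Near-identical copies were sought among these transcripts with blastn 2.17.0, at an identity of at least 95% over at least 50% of the transcript. The authors' normalized values and FPKM entered no test.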

Results

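The fro mutation is a deletion inside Smpd3, the gene for neutral sphingomyelinase 2, a membrane enzyme that releases ceramide from sphingomyelin. The series concerns this enzyme in brain ageing, and compares cortex of fro/fro with that of fro/+ mice at 10 months of age. Read counts per gene of 2 fro/+ libraries (23644600 and 21007254 counts) and 2 fro/fro libraries (25720347 and 24141910 counts) were available, with 18971 to 19503 genes detected in each. Pairs of libraries correlated at 0.968 to 0.981 (Pearson, across genes, log CPM), and no pair agreed within sampling noise.

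Smpd3 itself (ENSMUSG00000031906, chromosome 8, 106252548 to 106337988, minus strand, mm10) was read first. It had 1434 and 1114 counts in fro/+ 5 and 8 and 1077 and 996 in fro/fro 6 and 7, or 57.4 ± 6.74 CPM (SD, n = 2) against 41.3 ± 0.191 CPM. The log2 fold change of fro/fro over fro/+ was -0.48 (SE 0.12, edgeR adjusted p = 0.0756), so the gene did not pass at 0.05. Both fro/fro libraries lay below both fro/+ libraries. The count covers the whole gene, and reads outside the deleted part are counted in both genotypes, so it checks the genotype labels only in part. DESeq2 gave the same fold change with an adjusted p of 0.0246.

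Of 15586 genes tested, 342 passed at 0.05, 262 higher and 80 lower in fro/fro. The median change was 1.66-fold in both directions. An unadjusted p under 0.05 was found for 3655 of all tested genes (23.5%), 1990 higher and 1665 lower. Counts at that unadjusted p in the lists below are to be read beside this share. Gpr179, an orphan receptor known from signalling of retinal bipolar cells, had the largest rise among the called protein-coding genes that met the naming rule, from 0.705 ± 0.139 to 7.78 ± 0.0282 CPM (n = 2 each), and Rpl30, of the large ribosomal subunit, had the largest fall among them, from 143.2 ± 27.4 to 30.2 ± 1.37 CPM. Fold changes followed gene length: the median gene length was 8422.5 bp among genes called higher, 759.5 bp among those called lower and 3087.5 bp among all tested genes.

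Among genes that were higher, Grin2a, a subunit of the NMDA-type glutamate receptor, rose from 6.22 ± 0.0265 to 14.4 ± 1.78 CPM (log2 fold change 1.21, SE 0.19). The teneurins Tenm2 and Tenm3, adhesion proteins of synapses, rose by 1.21 and 1.10 on the log2 scale, and Ryr2, a calcium release channel of the endoplasmic reticulum, by 1.17. Map1b, a microtubule-associated protein, had a log2 fold change of 1.12 and was at 563.9 ± 124.1 CPM in fro/fro. The histone methyltransferase gene Kmt2a (1.12) and Tnrc6b (1.14), a component of microRNA silencing, were also higher, as were Rnf169 (1.26), a ubiquitin ligase, Tmem181a (1.33), Tmem245 (1.21) and D10Bwg1379e (1.19). Gpr179 (chromosome 11, 97332109 to 97352077, log2 fold change 3.46, SE 0.31) was detected with only 14 and 17 counts in fro/+. All 12 of these genes had edgeR adjusted p values of 0.0418 to 0.0427. With the gene length offset their log2 fold changes ran from 0.50 (Kmt2a) to 3.02 (Gpr179). The choice of length mattered for some of them. Grin2a had 1.04 with the gene length offset and 0.68 with the transcript length offset, and Tmem245 had 0.59 and 1.24.

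Among genes that were lower were several for small proteins of mitochondria: Pet100 (log2 fold change -1.30), an assembly factor of complex IV, and Atp5k (-1.05), Usmg5 (-1.04) and Atp5e (-0.96) of the ATP synthase. Tomm7 (-0.99), of the outer membrane import channel, and Mrpl27 (-0.99), of the mitochondrial ribosome, fell as well. Rps21 and Rps29, of the small ribosomal subunit, fell by 0.92 each on the log2 scale. The others were Naa38 (-1.26), a subunit of an N-terminal acetyltransferase, Rnaset2a (-1.14), a lysosomal ribonuclease, and Tmem256 (-1.03). Rpl30 (chromosome 15, 34440505 to 34443640) had a log2 fold change of -2.24 (SE 0.15) and the smallest edgeR adjusted p of all genes, 0.0135. With the gene length offset the 12 genes ran from -2.17 (Rpl30) to -0.49 (Rps21). Rnaset2a and Mrpl27 have near-identical copies elsewhere in the genome, and a pseudogene copies part of Rpl30, so these counts are uncertain where reads could go to either place.

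**Figure D1:**
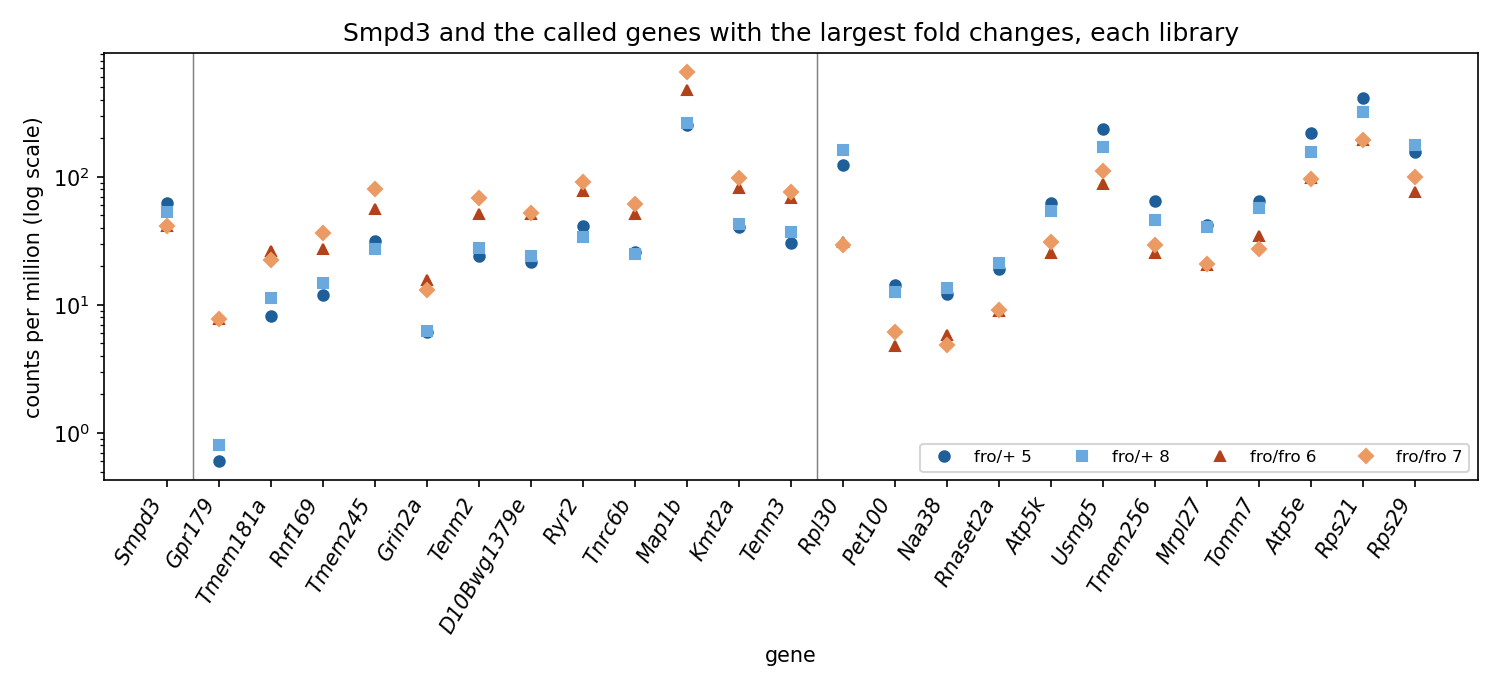
CPM (log axis) of Smpd3 (left), the 12 genes called higher (middle) and the 12 called lower (right) with the largest fold changes among protein-coding genes with a mean count of at least 50, 1 point per library, blue for fro/+ and orange for fro/fro. In each gene both fro/fro points lie on the same side of both fro/+ points.

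All 342 calls had both fro/fro libraries on one side of both fro/+ libraries, which 2 of the 6 possible orders of 4 libraries into pairs give by chance. With any 1 library left out all 342 kept the sign of their fold change, which such separation nearly ensures. Fewer genes passed in each of those fits, which also have fewer samples. Reliance of the calls on single libraries was therefore not told apart from sample number. With a per-library offset for gene length, chosen after the data were seen, 1 gene passed (Rpl30, log2 fold change -2.17, edgeR adjusted p = 0.0284). That call ended with the offset for transcript length (-1.89, edgeR adjusted p = 0.190) and with GC content added (edgeR adjusted p = 0.164). With the gene length offset the median size of the 342 changes went from 0.73 to 0.34 on the log2 scale at a median SE of 0.12 and 0.11.

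The relation to gene length was graded over the whole range. In the shortest decile of genes (66 to 1194 bp) the median log2 fold change was -0.40, with 58 genes called lower and 1 higher. In the longest decile (6383 to 106824 bp) it was 0.42, with 209 genes called higher and 0 lower by edgeR. The rank correlation of fold change with gene length was 0.55 across genes, which are not independent replicates. The slope of log2 expression per doubling of gene length, relative to the mean of the 4 libraries, was -0.15 and -0.07 in fro/+ 5 and 8 and 0.09 and 0.13 in fro/fro 6 and 7.

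**Figure D2:**
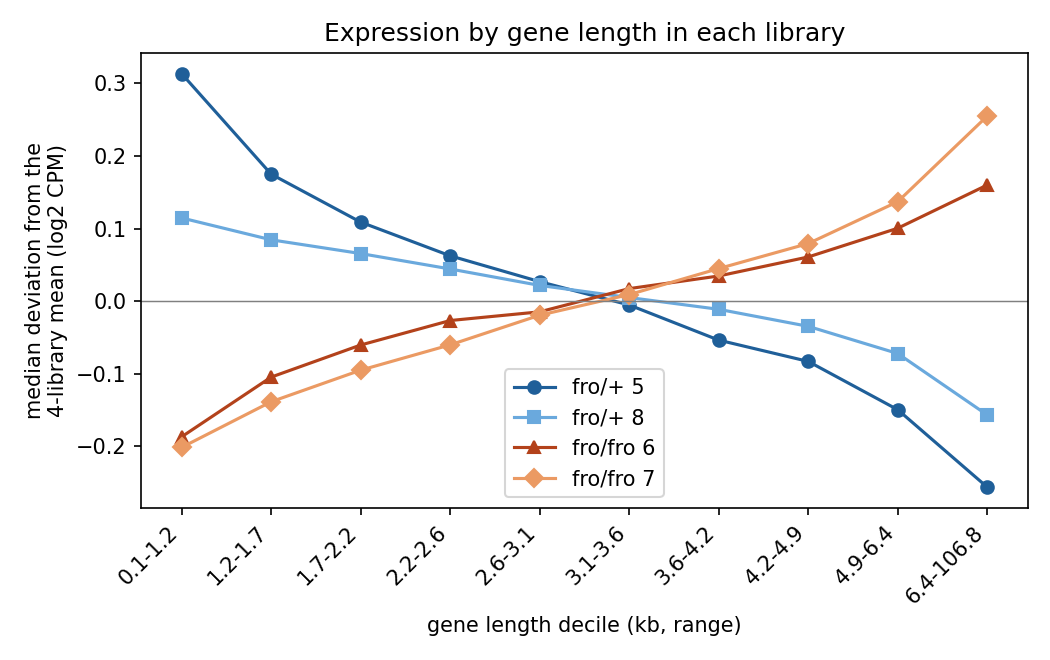
Median deviation of log2 CPM from the mean of the 4 libraries (vertical axis) in deciles of the tested genes by gene length in kb (horizontal axis), 1 line per library. In the longest decile the medians were -0.26 and -0.16 in the fro/+ libraries and 0.16 and 0.26 in the fro/fro libraries; the order was the opposite in the shortest decile.

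The lists of cytosolic ribosomal proteins and nuclear oxidative phosphorylation passed downward with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.49 for both). No list passed that test, which has few degrees of freedom here, so it cannot decide between lists. Of 82 cytosolic ribosomal protein genes tested, 9 were called lower and 0 higher by edgeR, and 76 were lower when adjusted over the list alone. Their median log2 fold change was -0.60 (camera adjusted p = 3.54e-43). Besides Rpl30, Rps21 and Rps29, Rpl38 had -0.85 and Rpl36 -0.86 (-0.42 each with the length offset). Of 79 genes of nuclear oxidative phosphorylation, 23 were called lower and 0 higher, and 65 were lower when adjusted over the list alone, with a median of -0.54 (camera adjusted p = 2.51e-40). Uqcr11 of complex III had -0.91, and Ndufa1 and Ndufa2 of complex I had -0.86 and -0.74 (-0.50, -0.43 and -0.34 with the length offset). These genes are short, with median lengths of 932.5 and 963 bp, and with the length offset the medians were -0.27 and -0.23 (camera adjusted p = 2.7e-21 and 2.35e-16; adjusted p = 0.719 for both with an estimated correlation). The 12 mitochondrially encoded genes tested had a median of -0.27 (camera adjusted p = 0.0324; adjusted p = 0.72 with an estimated correlation), with 0 called by edgeR, and mt-Nd1 had -0.49 (SE 0.25; -0.16 without fro/+ 5, -0.15 with the length offset). Their share of counts differed within genotype, at 4.65% and 3.45% in fro/+ 5 and 8 and 2.88% and 4.15% in fro/fro 6 and 7, and the list did not pass without fro/+ 5 (adjusted p = 0.339) or without fro/fro 6 (0.722), or with the length offset, where the median was 0.05 (0.876).

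The synaptic plasticity list had a median log2 fold change of 0.23 and passed upward (camera adjusted p = 2.49e-06), but not with an estimated correlation (adjusted p = 0.49) or with the length offset, where the median was 0.08 (camera adjusted p = 0.0878). Of 45 genes tested, 33 had positive and 12 negative fold changes, 3 were called higher and 0 lower by edgeR, and 17 were higher and 1 lower when adjusted over the list alone. The called genes were Grin2a, the calcium channel gene Cacna1c (log2 fold change 1.01, SE 0.18; 0.44 with the length offset) and the histone acetyltransferase gene Ep300 (0.81, SE 0.10; 0.38 with the offset). Its partner Crebbp had 0.62 (edgeR adjusted p = 0.0511; 0.14 with the offset). Immediate early genes, which report recent neuronal activity, had 0 of 33 called by edgeR, with 9 at an unadjusted p under 0.05 (6 higher and 3 lower), and a median of -0.03 while camera pointed upward (adjusted p = 0.77). Arc had -0.63 (SE 0.20), but -0.32 without fro/+ 5 and -0.89 without fro/+ 8, and Egr1 had 0.35 (SE 0.12; 0.21 with the offset).

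Genes of sphingolipid metabolism, Smpd3 among them, did not pass as a group. None of the 45 tested genes passed by edgeR, 8 had an unadjusted p under 0.05 (5 higher and 3 lower) and the median was -0.04 (camera adjusted p = 0.762). The ceramide synthase gene Cers6 had 0.67 (SE 0.16, edgeR adjusted p = 0.0654) and Sptssa, a subunit of serine palmitoyltransferase, -0.46 (SE 0.13); with the length offset they had 0.32 and -0.20. Neutral sphingomyelinase 2 is also known for a part in exosome release. Of 28 exosome and ESCRT genes 0 passed by edgeR, 8 had an unadjusted p under 0.05 and the median was -0.17 (camera adjusted p = 0.064). With the length offset the list median was -0.02 (camera adjusted p = 0.439). The tetraspanin genes Cd63 and Cd9 had -0.48 (SE 0.12) and -0.56 (SE 0.17), the syndecan gene Sdc4 had -0.49 (SE 0.12), and Pdcd6ip, which encodes the ESCRT adaptor Alix, had 0.39 (SE 0.11). With the length offset Cd63, Cd9 and Pdcd6ip had -0.14, -0.28 and 0.11, and Cd9 had -0.35 without fro/fro 7.

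Among lists of stress and ageing, the oxidative stress list passed downward (camera adjusted p = 6.38e-06; adjusted p = 0.49 with an estimated correlation) and the others did not pass. Of 40 oxidative stress response genes 0 passed by edgeR and 18 were lower and 1 higher when adjusted over the list alone, with a median of -0.30. Gpx1 had -0.72 (SE 0.16; -0.45 without fro/+ 5), Prdx1 -0.53 (SE 0.13) and Sod1 -0.48 (SE 0.10); with the length offset Gpx1 had -0.39 and Sod1 -0.083. The median with the length offset was -0.09 (camera adjusted p = 0.0145; adjusted p = 0.719 with an estimated correlation). Of 33 heat shock and unfolded protein response genes 1 was called lower, the mitochondrial chaperonin gene Hspe1 (-0.71, SE 0.14; -0.37 with the offset), and Manf had -0.46 (edgeR adjusted p = 0.0571); the list did not pass (camera adjusted p = 0.0625). The 27 senescence and SASP genes tested had 0 calls by edgeR, 4 at an unadjusted p under 0.05 and a median of -0.07 (camera adjusted p = 0.574); Cdkn1a, the cell cycle inhibitor p21, had -0.39 (SE 0.16; -0.22 without fro/fro 6, -0.24 with the offset) and Ets2 0.48 (SE 0.15). Among 21 amyloid and brain ageing genes, Apoe was called lower, from 3894.8 ± 100.9 to 2598.9 ± 6.81 CPM (-0.58, SE 0.11; -0.34 with the offset), and the list did not pass (camera adjusted p = 0.116).

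The lists of astrocyte and microglia markers passed downward with the preset correlation, but not with an estimated correlation (adjusted p = 0.49 for both). They were the 2 lists that passed with fry (fry adjusted p = 0.0172 and 0.0049). Fry was run without the length offset and does not compare a list with other genes. Of 19 astrocyte markers 15 had negative fold changes, 1 passed and 6 were lower and 1 higher when adjusted over the list alone. The gene that passed was S100b, a calcium-binding protein of astrocytes, at 267.7 ± 27.2 CPM in fro/+ and 175.04 ± 1.27 CPM in fro/fro (-0.61, SE 0.11; -0.38 with the length offset). Ppp1r3c had -0.50 (SE 0.11), Aldoc -0.47 (SE 0.12) and Mlc1 -0.41 (SE 0.11). The median was -0.25 (camera adjusted p = 0.0037) and was -0.27 with the length offset (camera adjusted p = 7.25e-07; adjusted p = 0.719 with an estimated correlation). Of 25 microglia markers 0 passed by edgeR, 8 had an unadjusted p under 0.05, all lower, and 1 was lower when adjusted over the list alone. Among all tested genes 23.5% had an unadjusted p under 0.05. The complement genes C1qa and C1qc had -0.51 (SE 0.10) and -0.43 (SE 0.12), and Aif1 had -0.90 (SE 0.25); with the length offset they had -0.19, -0.15 and -0.54. The median was -0.12 (camera adjusted p = 0.0145) and the list did not pass with the length offset (0.378) or without fro/+ 8 (0.0502). Genes of reactive astrocytes (31 tested, camera adjusted p = 0.675) and of the interferon response (33 tested, 0.236) had 0 calls by edgeR, with 1 and 2 genes at an unadjusted p under 0.05.

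Other cell type and region markers differed between libraries of the same genotype. The 25 oligodendrocyte and myelin genes had a median of -0.36 (camera adjusted p = 0.0095; adjusted p = 0.72 with an estimated correlation) with 0 calls by edgeR and 2 at an unadjusted p under 0.05. Their per-library medians were 0.59 and -0.12 in fro/+ 5 and 8 and 0.24 and -0.70 in fro/fro 6 and 7, relative to the mean of the 4 libraries. The list did not pass without fro/+ 5 (adjusted p = 0.308) and pointed upward without fro/fro 7 (0.931). Myelin basic protein gene Mbp had 171291, 98571, 118257 and 66589 counts in fro/+ 5 and 8 and fro/fro 6 and 7, and Hapln2 had a log2 fold change of -1.27 (SE 0.27, edgeR adjusted p = 0.0655). The 23 striatum markers had a median of -0.59 (camera adjusted p = 0.0368; adjusted p = 0.75 with an estimated correlation) with 0 calls and 0 genes at an unadjusted p under 0.05 by edgeR; the per-library median was 0.98 in fro/+ 5 and between -0.44 and -0.07 in the rest, and the list pointed upward without fro/+ 5 (adjusted p = 0.0361) and did not pass without fro/fro 7 (0.273). Tac1 and Penk, neuropeptide genes of striatal projection neurons, had -0.88 (SE 0.46) and -0.59 (SE 0.32), but -0.13 and -0.074 without fro/+ 5.

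The 29 excitatory neuron markers had a median of 0.19 (camera adjusted p = 0.0182; adjusted p = 0.51 with an estimated correlation), with 0 calls by edgeR, 10 at an unadjusted p under 0.05 (9 higher), and the cortical transcription factor gene Tbr1 at 0.58 (SE 0.14; 0.38 without fro/fro 6). The list did not pass without fro/fro 6 (0.206) or with the length offset (0.0661). The 29 inhibitory neuron markers did not pass (camera adjusted p = 0.612), and Sst, the somatostatin gene, had -0.52 (SE 0.11; -0.12 with the length offset). Of 18 circadian clock genes 16 had positive fold changes and 1 was called, the clock repressor gene Nr1d1 (0.62, SE 0.12). The median of the clock list was 0.28 (camera adjusted p = 0.0083, and 0.49 with an estimated correlation). It fell to 0.19 with the gene length offset (camera adjusted p = 0.0145) and to 0.18 with the transcript length offset (0.0405). Per3 had 0.45 (SE 0.13; 0.17 with the offset). The 8 blood cell genes had a median of -0.49 (camera adjusted p = 0.0095; adjusted p = 0.51 with an estimated correlation), with 0 called by edgeR and 3 at an unadjusted p under 0.05, and did not pass without fro/fro 6 (0.185) or with the length offset (0.0661).

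The remaining lists did not pass. Among them were oligodendrocyte precursor markers (camera adjusted p = 0.0749) and hippocampus markers (0.111). Of the precursor markers, the extracellular matrix gene Tnr was called higher (1.08, SE 0.13) and Rlbp1 had -0.60 (SE 0.14). Tnr had 0.95 with the gene length offset and 0.58 with the transcript length offset, and passed with neither. Of the hippocampus markers, Zbtb20 was called (0.74, SE 0.13, and 0.06 with the length offset). Endothelial and mural markers (0.825) had a median of -0.10 while camera pointed upward, and Myh11 of smooth muscle had 1.32 (SE 0.26, edgeR adjusted p = 0.0511); that list passed upward without fro/+ 5 (0.000481) and downward without fro/+ 8 (0.018). Thalamus markers (0.0749), meninges and fibroblast markers (0.0515), choroid plexus markers (0.0794) and cholesterol synthesis genes (0.384) had 0 calls by edgeR, with 3, 0, 1 and 6 genes at an unadjusted p under 0.05. Cyp51 of the last list had -0.45 (SE 0.13).

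**Figure D3:**
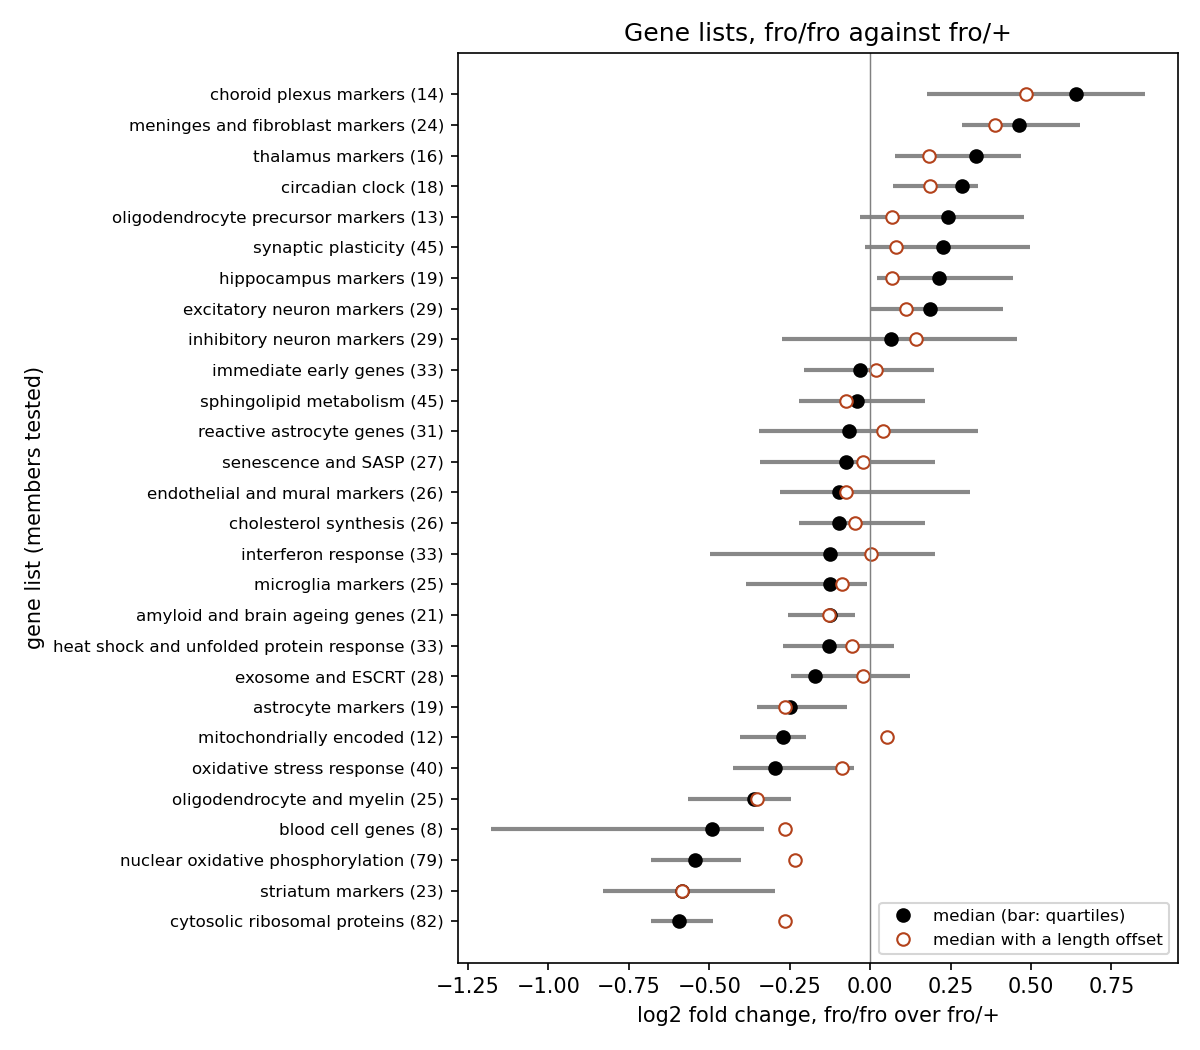
Log2 fold change of fro/fro over fro/+ (horizontal axis) for 28 gene lists, with the number of tested members in brackets. Filled points are medians over members, bars the quartiles and open points the medians with a length offset; the ribosomal list moved from -0.60 to -0.27 and the astrocyte list from -0.25 to -0.27.

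The background label raises the question of sequence linked to the mutant allele. Within 10 Mb of Smpd3 on chromosome 8, Nfat5, an osmotic stress transcription factor (log2 fold change 0.89, SE 0.14), and Glg1, a Golgi glycoprotein (0.72, SE 0.11), were called higher (0.32 and 0.38 with the length offset). They were 2 of 132 tested genes there (1.52%), against 340 of 15454 elsewhere (2.2%), an odds ratio of 0.68 (95% interval 0.08 to 2.54; two-sided Fisher's exact p = 1). At an unadjusted p under 0.05 the counts were 26 and 3629 (odds ratio 0.80, Fisher's exact p = 0.353).

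The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed in all 4 libraries, Ddx3y at 1271 to 1561 counts, and Xist had 4 to 20 counts. The log2 fold changes of the 4 Y-linked genes lay between -0.23 and 0.01 and none passed by edgeR.

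An adjusted p under 0.05 is given to 1462 genes by the authors' deposited table, 891 higher and 571 lower in fro/fro. Of the 342 genes called by edgeR, 338 were among them with the same sign, and 1124 passed only in the authors' deposited table. The authors' deposited table gives Smpd3 a log2 fold change of -0.43 and an adjusted p of 0.0354. Both come from the same counts, so this compares tools and not data.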

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

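The gene length offset and both transcript offsets were chosen after the data were seen, and the other alternatives before. Covariates for sex-linked expression were not run because its level did not split the libraries, and a pseudocount did not apply to counts.

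The number of genes higher was 957 with DESeq2, 1059 with no filter, 937 at an adjusted threshold of 0.10, 131 with upper-quartile scaling, and 0 with each of the 3 offsets (1934, 1854 and 1843 genes at an unadjusted p under 0.05 by edgeR, with gene length, transcript length, and transcript length with GC). The number lower was 660 with DESeq2, 698 with no filter, 149 at a mean count of at least 50, 603 at 0.10, 1 with the gene length offset, and 0 with both transcript offsets. Upper-quartile scaling left 61.5% of calls higher, against 76.6%, with a median shift of -0.06 over all genes. Leaving out 1 library gave 0 to 109 genes higher and 2 to 13 lower; of the 342 calls, 2 were shared without fro/+ 5, 2 without fro/+ 8, 85 without fro/fro 6 and 2 without fro/fro 7. The lone library of a genotype is then assumed to vary like the others. DESeq2 shared 334 of the 342, limma-voom 325, RLE scaling 307 and upper-quartile scaling 210. Tests without a library have fewer samples by construction; the cause of the changes was not tested.

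Smpd3 stayed lower in every alternative. It passed with DESeq2 (-0.48) and with no filter (-0.47), and had -0.60 to -0.36 with 1 library left out and -0.71 to -0.69 with the offsets. The odds ratio near Smpd3 was 1.11 with upper-quartile scaling (Fisher's exact p = 0.702) and 0 to 0.95 with 1 library left out; with both transcript offsets it had no value since 0 genes passed.

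The number of lists higher was 3, with 5 under upper-quartile scaling, 5 with no filter, 0 with an estimated correlation, 0 with fry, and 3 to 8 with 1 library left out. The number of lists lower was 9, with 0 under an estimated correlation, 2 with fry, and 6 to 10 with 1 library left out. Lists of ribosomal, oxidative phosphorylation, oxidative stress, astrocyte and circadian genes passed in each camera test with the preset correlation.

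Directions turned in these cases, for causes not tested, given as camera adjusted p; ranges are over 1 library left out. Mitochondrially encoded genes pointed upward with the 3 offsets (0.876, 0.805 and 0.294), as did reactive astrocyte genes (0.890, 0.891 and 0.833; 0.361 without fro/+ 8, 0.885 without fro/fro 6, range 0.197 to 0.885) and, with both transcript offsets, senescence genes (0.902 and 0.833). Without fro/+ 5 the turned lists were sphingolipid (0.900, range 0.195 to 0.900), immediate early (0.603, range 0.236 to 0.626), inhibitory neuron (0.786, range 0.192 to 0.931), striatum (0.0361, range 8.53e-22 to 0.273) and meninges (0.339, range 9.6e-16 to 0.339). Without fro/+ 8 the endothelial list turned (0.018, range 0.000481 to 0.931), and without fro/fro 7 sphingolipid (0.528), immediate early (0.626), myelin (0.931, range 4.76e-14 to 0.931) and endothelial (0.931). Kdm5d (log2 fold change 0.01) had -0.042 with upper-quartile scaling, -0.39, -0.37 and -0.36 with the offsets, -0.064 without fro/+ 5 and -0.15 without fro/fro 7 (range -0.15 to 0.16). Of 532 values of named genes under other tests, scalings and filters, Kdm5d included as the 1 that turned, 470 kept their side of the threshold, 53 passed only there and 8 passed only in the reported test; DESeq2 gave 8 named genes no adjusted p. The 39 named genes that passed have 156 values with 1 library left out, of which 134 no longer passed, and 117 with the offsets, of which 116 no longer passed.

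With 2 libraries per genotype, 36 of 50 simulated 2-fold changes and 16 of 50 simulated 1.5-fold changes were recovered by edgeR. The same simulation gave 26 false calls, a larger share of its calls than the adjusted threshold is meant to allow. That simulation held no length trend and no difference in tissue between libraries, so recovery and false calls in these data may differ.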

Other observations

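The 3 offsets and the tests on length recovery, on linkage to Smpd3 and on the astrocyte list were chosen only after the related values were seen; the others were fixed before their result was seen. Genes named in this part outside the naming rule were chosen after their values were seen.

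Markers of tissue next to the cortex differed between single libraries. The choroid plexus gene Ttr had 1087 counts in fro/fro 7 and 211 to 324 in the rest, and Otx2 had 78 and 16 counts in fro/fro 6 and 7 and 6 and 5 in fro/+. The median over 24 meninges and fibroblast markers, relative to the mean of the 4 libraries, was -0.86 in fro/+ 5 and 0.27 to 0.36 in the rest, while the median over striatum markers was 0.98 in fro/+ 5. With the length offset both the choroid plexus list (median 0.49) and the meninges list (0.39) had a camera adjusted p of 0.0073, and adjusted p values of 0.719 and 0.722 with an estimated correlation.

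The length trend was the broadest pattern in these data. A change confined to neuronal genes is argued against: across 132 markers of astrocytes, microglia, oligodendrocytes, their precursors, vessels and meninges the rank correlation of fold change with transcript length was 0.54 (permutation p = 1e-05, the smallest that 100000 permutations can give; genes are not independent). Long genomic span in place of long transcripts is also argued against, since the partial rank correlation was 0.45 for transcript length and 0.09 for span, a difference of 0.36. Recovery of RNA by length that differs between libraries, from RNA integrity or library preparation, stays open: libraries of the same genotype differed along transcript length too, with rank correlations of 0.22 for the fro/+ pair and 0.0972 for the fro/fro pair, but those between genotypes were 0.43 to 0.50. Genotype and such a technical difference cannot be told apart here, because the trend followed genotype in all 4 libraries and no RNA quality value was used here.

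The largest single-gene changes may partly reflect how reads divide between near-identical copies. The test that follows did not match genes on count level or gene type, so it cannot separate read division from other traits of copies. Of 19 genes with a log2 fold change of at least 1.5 in size and p under 0.01, 6 (31.6%) had a near-identical copy, against 604 of 15567 other genes (3.88%), an odds ratio of 11.4 (95% interval 3.55 to 32.4, two-sided Fisher's exact p = 6.15e-05). Linkage to the mutant allele as the source of most of these changes is argued against, as 0 of the 19 (0%) lay within 20 Mb of Smpd3. That window held only 326 of the 15586 tested genes. The test says nothing about C3H or C57BL/6 sequence elsewhere in the genome. The pseudogene Gm6969 (chromosome 12, 24638669 to 24639010) had 2471 and 1011 counts in fro/+ and 3 and 1 in fro/fro. Its parent Cox7a2l, a respiratory supercomplex factor on chromosome 17, had 3853, 3869, 4551 and 4139. After scaling, Cox7a2l had a log2 fold change of -0.016 (SE 0.10). Its principal transcript is 1076 bp long, and tested genes of 66 to 1194 bp had a median of -0.40. A flat value for a gene this short could hide a loss of Cox7a2l counts in fro/+, which was not tested. Gm6969 carries 6 bases, in 1 gap of the alignment, that the mm10 transcript of Cox7a2l lacks. The Cox7a2l allele of C57BL/6 is known to be shorter by that number than that of other strains. A candidate explanation is that the fro/+ libraries, and not the fro/fro libraries, hold the longer allele of Cox7a2l, whose reads then align to the pseudogene; the reads were not analysed here, and genotype as the cause stays untested.

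Counts of further copies are given here; Gm6304 and Gm5540 passed by edgeR, and Rnaset2b (adjusted p = 0.0602), Hba-a2 (0.0622) and Gm12191 (0.612) did not. Gm6304, a copy of Mrpl27 (98.9% over 447 bp), had 9 and 0 counts in fro/+ and 170 and 135 in fro/fro, where Mrpl27 was lower. Gm5540, a copy of Acsf2, had 8 and 2 against 53 and 59 counts, while Acsf2 had 681, 639, 679 and 557. Rnaset2b had 16 and 8 against 54 and 80 counts, opposite to its copy Rnaset2a with 436 and 448 against 233 and 222. Gm12191, a copy of part of Rpl30 (99.7% over 348 bp), had 529 and 28 counts in fro/+ 5 and 8 and 825 and 807 in fro/fro, where Rpl30 was lower. Summed over the libraries of a genotype, Gm12191 rose from 557 to 1632 counts while Rpl30 fell from 6298 to 1521. Reads moving to this copy could therefore account for only part of the fall of Rpl30. The globin gene Hba-a2 had 12 and 60 against 0 and 1 counts beside 3607, 1204, 1624 and 2284 for its copy Hba-a1 (log2 fold change -0.45, SE 0.61), so this pair shows no opposite division.

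The astrocyte list passed downward with and without the length offset. It did not pass with an estimated correlation (adjusted p = 0.719 and 0.49), a test that no list passed without the offset. The list was picked out because it stayed lower with the offset, so its passing there is no test of the length trend. Its median gene length was 2880 bp, near the 3087.5 bp of all tested genes, so an offset could hardly move it. The median with the offset was 1.07 times that without it. Tested genes of 2649 to 3087 bp had a median log2 fold change of -0.04, against -0.25 in the list. Whether every glial type fell alike cannot be decided here. With the offset the astrocyte median lay 0.18 below that of microglia markers on the log2 scale (a difference of -0.18, permutation p = 0.00091). That p measures spread over genes, which are not independent, and not over libraries. Without the offset the library medians were close. They were 0.10 and 0.10 in fro/+ and -0.10 and -0.14 in fro/fro for astrocyte markers, and 0.05, 0.12, -0.07 and -0.10 for microglia markers. Precursor markers had a median of 0.07 with the offset. Myelin genes had a median of -0.35 with the offset (camera adjusted p = 0.0095, and 0.736 with an estimated correlation), but their library medians without it, 0.59 and -0.12 in fro/+ and 0.24 and -0.70 in fro/fro, did not split by genotype. A lower astrocyte share, alone or with other glial types, lower expression per astrocyte and a difference in the piece of cortex taken all stay open.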
